A study of Neurospora crassa with 5 samples.

How the data were processed

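The series holds Hi-C of 4 strains of Neurospora crassa and 1 ChIP-seq sample of mCherry-tagged CenH3. Per the labels, conidia were grown for 3 to 4 h at 30 °C and crosslinked with 1% formaldehyde for 10 min, DNA was cut with HindIII, ends were filled with biotinylated dCTP, and ligated fragments were purified and sequenced. Replicates are pooled in 1 array per strain. The submitters' processing notes name SAMtools, with no version. The aligner of the Hi-C reads, read filters, balancing tool and number of read pairs are not given in the sources used here.

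The deposited contact arrays hold signal, the contact between pairs of 10-kb or 50-kb bins. Tested on the values, they are square and symmetric, and all non-empty bins of an array have the same total (3450 in wild type, 2489 in dim-5, 1873 in hpo and 1040 in dim-3 at 10 kb), so the bins were balanced within each array. The wild-type total was 1.39, 1.84 and 3.32 times that of dim-5, hpo and dim-3. The deposited observed/expected arrays hold a linear ratio at 10 kb, for all reads and for subsets sampled by the authors (M standing for 10 to the power of 6, wild type 16.5 M and 30 M reads, dim-5 30 M, hpo 49 M, from their names). Their means range from 0.439 to 0.911, so each was rescaled as described below. The wild-type array of 16.5 M reads has 44 empty bins against 93 for all reads and a lowest bin sum of 111 against 2433, so it was filtered differently. The deposited ChIP-seq tracks hold signal per 1-kb window. The text describing the CenH3 ChIP-seq is attached to the dim-3 sample in the labels, and the track was taken to come from the tagged strain that the title and genotype of the CenH3 sample name. Their scaling is not given, and the H3K9me3 and H3K27me3 tracks were made by the authors from raw data of another series. The strain and growth behind those tracks are not given in the sources used here. The 40-kb arrays, present for wild type, and the 50-kb observed/expected arrays were not used.

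Bins were assigned to chromosomes I to VII from the ends of the CenH3 track. The assignment was checked on the arrays: all 24 boundaries tested (6 in each of 4 strains) lay within 2 bins of a local low in contact across the boundary, at 17.6% of the median or less. Coordinates are those of the deposited annotation (assembly 12 of OR74A, 1-based). Gene symbols came from a RefSeq table of assembly NC12, which matched 9729 of 9730 locus tags, 9491 with identical spans. Another 238 genes, all in VI 1851685 to 2769626, run in reverse order between both sources. Contact across the segment's ends in wild type was −0.18 and −1.65 (log2 over expected) in the deposited order and −6.61 and −5.60 in the reverse order, so the deposited order was kept and RefSeq was used for names alone.

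The following choices, the tests and the alternatives in the first list below were fixed before the data were examined. A bin without contacts in at least 1 of the 4 arrays was left out of all of them. A centromere was the run of bins within 150 kb of the CenH3 peak (highest median over 5 bins), from the first to the last with 25% of the peak signal. Telomere bins were the terminal 50 kb. Marked bins had a signal above Otsu's threshold on log2(signal + 1), 7.69 for H3K9me3 and 32.3 for H3K27me3, outside centromeres with 50-kb flanks and outside telomeres. H3K27me3 bins with H3K9me3 were not counted as H3K27me3. Enrichment was log2 of summed observed over summed expected contact. Expected contact was the mean at the same distance over all chromosomes, or the mean of all pairs between chromosomes. Pairs on 1 chromosome were at least 100 kb apart, and pairs within domains 20 to 50 kb apart in 1 run of marked bins with gaps of 1 bin bridged. The decay exponent was the slope of log10 contact on log10 distance over 12 log-spaced steps from 50 kb to 1 Mb. The share of contacts between chromosomes left out the diagonal and the first off-diagonal. The leading component came from the correlation matrix of observed/expected contact per chromosome, and its sign on each chromosome was set by H3K9me3. Differences are mutant minus wild type. Intervals are 95% delete-1-chromosome jackknife intervals (t distribution, 6 degrees of freedom), a description of variation along the genome. In addition, the classes of bins were shifted at random along the chromosomes 200 times.

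Regions named in the text were the 7 centromeres, the 14 chromosome ends, the 10 longest interstitial domains of each mark, for each mutant the 5 pairs of H3K9me3 domains with the largest decrease and the 5 with the largest increase (same direction in ratio arrays taken as similar in number of reads), and 12 genes fixed in advance. A match in depth was not shown for the ratio arrays of hpo and dim-3. Other regions were chosen after their values were seen, as were contacts across domains, by distance, by arm position and with other classes of bins.

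The alternatives fixed at that time were the authors' ratio arrays for all reads and for similar numbers of reads, 50-kb arrays, the median of single pairs of bins, each chromosome left out in turn, the CenH3 peak with 50 kb on either side as centromere, terminal 100 kb, marked bins by rank (15% of bins for H3K9me3, 7% for H3K27me3), a minimum distance of 300 kb, the 5% of bins with fewest filled entries left out (197 bins), decay over 20 to 500 kb, and pairs under 50 kb left out of the share. From ratio arrays, enrichment was the log2 of the mean ratio of the class over the mean of all pairs of the same kind. Added after the data were seen were the left end of chromosome V left out, dim-3 against wild type sampled to 30 M reads, contact within H3K9me3 domains in hpo against that array, dim-3 against the sparsest wild-type array with poorly filled bins left out, and H3K9me3 contact between chromosomes without pairs over 16 times the mean. A partial rho across domains, also added then, is the correlation of ranks after a linear fit on the ranks of the other measures was taken off both. The calculation was tested on simulated data: in 5 simulated pairs of arrays, with the changed array at 0.4 times the depth, 15 of 15 planted differences were called, with errors of at most 0.060 on the log2 scale, and 0 of 25 comparisons with nothing planted were called, with values of up to 0.085 for telomeres with centromeres and 0.023 for the other contacts. At 0.3 times the depth, simulated after the data were seen, 15 of 15 and 1 of 25 were called, with errors of up to 0.063 and, with nothing planted, 0.093 for telomeres with centromeres and 0.042 for the other contacts. The simulated counts were Poisson draws around the wild-type mean at each distance, alike on all chromosomes apart from added centromere and telomere contact and the planted differences. They were not balanced and held no difference between libraries. The counts of calls and the errors therefore check the calculation and do not carry over to differences between strains. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.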

Results

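Chromosome conformation capture (Hi-C), which counts how often pairs of genomic positions are ligated to each other after crosslinking, was performed on germinated conidia of the filamentous fungus Neurospora crassa. The 4 strains were a wild type (NMF39) and 3 mutants with defects in heterochromatin. The strain dim-5 lacks the histone methyltransferase that makes H3K9me3, hpo lacks heterochromatin protein HP1, which binds that mark, and dim-3 carries a mutation in importin alpha, a carrier of proteins into the nucleus. Per the labels, at least 3 replicates of the wild type and at least 2 of each mutant were made, but each strain is held in 1 contact array, so no value below has a replicate error and no p-value can be given. A ChIP-seq track of the centromeric histone CenH3, per its labels from a separate tagged strain, marked the centromeres. Tracks of H3K9me3 and H3K27me3, which come from samples of another study, marked heterochromatin. The same marked bins were used in all 4 strains. An H3K9me3 bin or domain is thus a position marked in that study, and the mark was not measured in the mutants.

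The 10-kb arrays held 4049 bins on the 7 chromosomes and 64 bins on unplaced sequence. All non-empty bins of an array had the same total contact after balancing. The summed contact, divided by 10 to the power of 6, was 13.9 in wild type, 10.0 in dim-5, 7.53 in hpo and 4.18 in dim-3. The total number of read pairs is not given, and the share of pairs of bins on different chromosomes with no contact served as a measure of sparsity. It was 42.0% in wild type, 51.3% in dim-5, 59.4% in hpo and 64.7% in dim-3. Because more of the dim-3 contact lay between chromosomes, this share may understate how sparse dim-3 is on 1 chromosome. There, mean contact at about 55 kb was 4.52 in dim-3, 17.6 in hpo, 22.8 in dim-5 and 32.0 in wild type. The depth behind each value is unknown. Bins with contacts in all 4 arrays numbered 3924, or 96.9% of the chromosomal bins.

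Most chromosomal bins fell into 5 classes with different gene content. The 171 centromere bins held 0.35 genes per 100 kb and the 547 interstitial H3K9me3 bins 7.75, against 28.0 in the 2892 bins with neither mark, called euchromatin here. The 299 interstitial H3K27me3 bins held 31.1 genes per 100 kb, and the 70 bins of the terminal 50 kb of the chromosomes held 20.4. With contacts in all 4 arrays, 160 centromere, 519 H3K9me3, 2822 euchromatin, 291 H3K27me3 and 68 terminal bins were used. Contact was expressed as enrichment, the log2 of summed observed over summed expected contact, where expected is the mean at the same distance on a chromosome or the mean of all pairs between chromosomes. Rises and falls between chromosomes are therefore relative to each strain's own mean. That mean was a larger part of a bin's total in dim-3 (0.203 of 1040) than in wild type (0.473 of 3450). Each enrichment and each difference between strains is given as the value ± the reach of its 95% interval from a jackknife that leaves out each of the 7 chromosomes in turn. This interval covers variation along the genome only, not variation between cultures or libraries, and a contact is said to rise or fall where the interval excludes 0.

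The first comparison asked whether centromeres stay clustered when heterochromatin is impaired. In wild type, centromeres of different chromosomes contacted each other 12.2-fold more often than other positions (log2 3.61 ± 0.21), with enrichment in all 21 pairs of chromosomes. Relative to the mean between chromosomes, centromere contact fell by 45.8% in dim-3 (log2 difference −0.88 ± 0.11), and it was lower in 21 of 21 chromosome pairs. As a part of a bin's total the fall was smaller, because that mean was a larger part of the total in dim-3. In dim-5 and hpo no change was detected, with differences of 0.03 ± 0.11 and 0.06 ± 0.12. Differences between mutants were 0.92 ± 0.17 for dim-5 minus dim-3 and 0.94 ± 0.16 for hpo minus dim-3.

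Each of the 7 centromeres took part in this. CenH3 peaks stood at 732 to 823 units of signal against chromosome medians of 2.41 to 2.85, and they marked chromosome I 3740001 to 3970000, II 1130001 to 1370000, III 690001 to 930000, IV 880001 to 1080000, V 980001 to 1220000, VI 2830001 to 3080000 and VII 2160001 to 2470000 in the coordinates of the deposited annotation (assembly 12 of strain OR74A). The loss in dim-3 ranged from −0.84 at the centromere of chromosome VII to −0.94 at that of chromosome IV, where 13 bins were usable. Against the wild-type ratio array sampled to 16.5 M reads the dim-3 difference was smaller, at −0.34, and that array left 73.2% of pairs between chromosomes empty against 64.6% in the dim-3 ratio array.

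**Figure D1:**
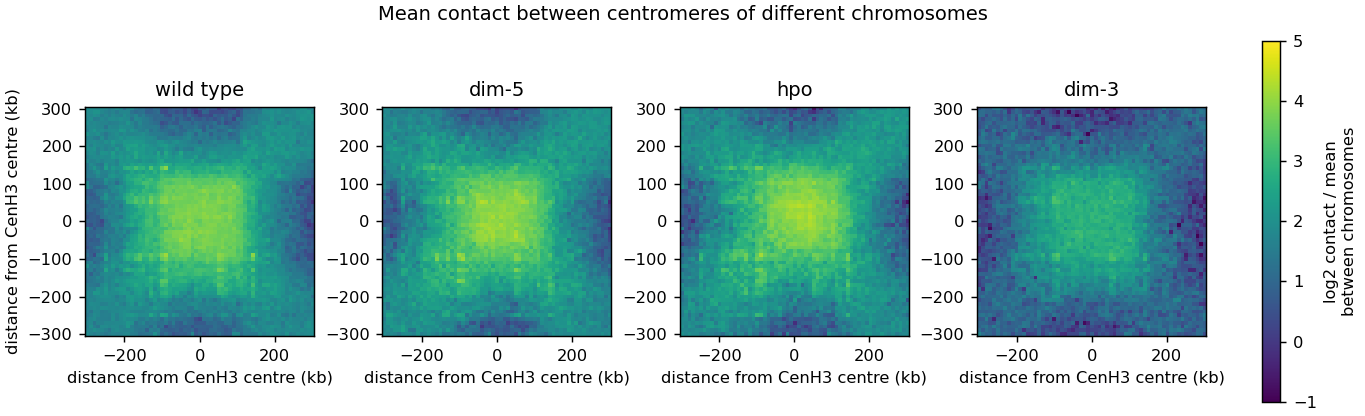
Mean contact around the CenH3 centres of all pairs of different chromosomes, in 10-kb bins, in the 4 strains; both axes give the distance from the centre in kb and the colour gives log2 contact over the mean between chromosomes. The central square of high contact is weaker in dim-3, where centromere contact fell by 0.88 on the log2 scale, than in the other 3 strains.

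The second comparison concerned the chromosome ends. In wild type, terminal 50-kb segments of different chromosomes contacted each other 8.23-fold more often than other positions (log2 3.04 ± 0.43). Telomere contact fell by 18.7% in dim-5 (−0.30 ± 0.13; lower in 21 of 21 chromosome pairs), and in dim-3 it fell by 57.1% (−1.22 ± 0.26, also lower in 21 of 21). As for centromeres, the dim-3 fall was smaller as a part of a bin's total. No change was detected in hpo (−0.07 ± 0.20), and the direct difference between dim-5 and hpo was −0.23 ± 0.15. The dim-3 difference was −0.66 ± 0.51 against the wild-type ratio array with the fewest reads and −2.10 as a median of single pairs of bins.

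One end stood apart in wild type. Of the 14 ends, 13 had an enrichment of 2.99 to 3.38, and the left end of chromosome V (positions 1 to 50000) had 0.49. In dim-5, 13 of 14 ends were lower, most of all the left end of chromosome II (−0.51), and the left end of V was higher (0.38). In dim-3 all 14 ends were lower, from −0.16 at the left end of V to −1.40 at the right end of II, and in hpo 10 of 14 were lower. Both ends of 1 chromosome also met, at log2 4.50 over the mean between chromosomes for chromosome II and 4.52 for VII, but at 0.71 for V. The left end of V had the highest H3K9me3 signal of all ends, 33.7 units, with 10 annotated genes. In wild type, 11 bins of unplaced sequence also had their strongest contact with the first 200 kb of V, as described below. Whether this assembled end is the end of the chromosome, and why its contact was low, was not tested.

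**Figure D2:**
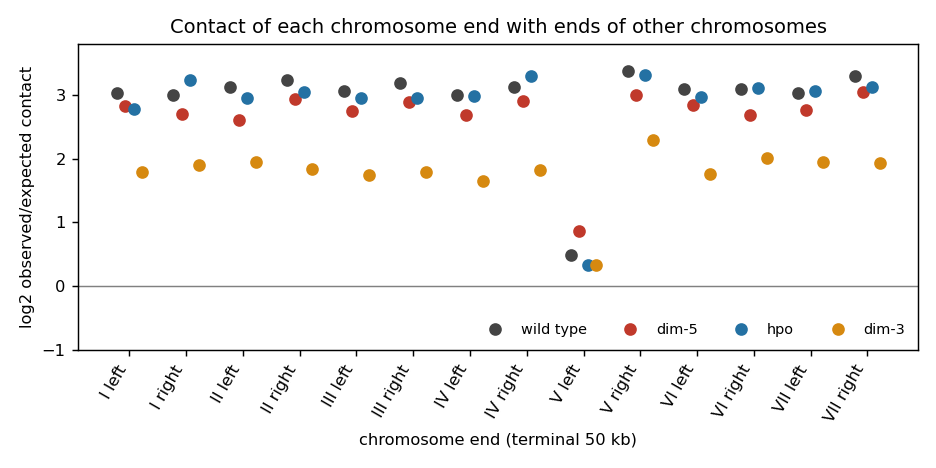
Enrichment (log2 observed over expected) of contact between each of the 14 chromosome ends (terminal 50 kb, x axis) and the ends of other chromosomes, with 1 point per strain. The left end of chromosome V lies at 0.49 in wild type against 2.99 to 3.38 for the other 13, and dim-3 has the lowest point at every end.

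Telomeres and centromeres met less often than their own kind. The wild-type enrichment was −0.33 ± 0.61, an interval that holds 0, but it was above 0 in 2 of 21 chromosome pairs alone, and 0 of 200 random shifts of the classes along the chromosomes gave a value as low. Contact between telomeres and centromeres rose in dim-5, by 0.20 ± 0.15 and in 16 of 21 chromosome pairs. The dim-3 difference was of the same size (0.20 ± 0.27) and higher in 17 of 21 pairs, with an interval that holds 0, and 0 of 200 shifts gave a value as high in either strain. The hpo difference was 0.02 ± 0.07. The difference between dim-5 and hpo was 0.18 ± 0.17. The dim-5 difference from wild type was 0.08 in the ratio arrays of all reads.

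The third comparison addressed the inside of interstitial heterochromatin. Contact between bins 20 to 50 kb apart within 1 H3K9me3 domain fell by 26.8% in dim-5 (−0.45 ± 0.11) and by 21.6% in hpo (−0.35 ± 0.06), in each case on all 7 chromosomes. In dim-3 the difference was 0.01 ± 0.14. Directly compared, dim-5 minus dim-3 was −0.46 ± 0.15 and hpo minus dim-3 was −0.37 ± 0.14, while the interval of dim-5 minus hpo holds 0 (−0.10 ± 0.13). In wild type, contact within the domains was close to that of other bins at the same distance (0.08 ± 0.24), although 1 of 200 shifts gave a value as high. The values rest on 382 pairs of bins, and against the wild-type ratio array with the fewest reads the dim-3 difference was 0.76.

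Of the 215 H3K9me3 domains, 141 had at least 2 bins, and the longest spanned 120 kb at II 3600001 to 3720000. Among the 10 longest, contact within the domain was lower than in wild type in 10 of 10 in dim-5 (median −0.34), in 9 of 10 in hpo (median −0.28) and in 8 of 10 in dim-3 (median −0.13, range −0.51 to 0.39). The largest single loss was −0.89 in dim-5 at IV 4230001 to 4300000, a domain of 4 genes that includes the phosphatase gene pho-3 (NCU08643), where hpo had −0.50. The domain at VI 1750001 to 1850000 holds 15 annotated genes, among them ckb-1 (NCU05485), a casein kinase subunit gene, and acu-6 (NCU09873), which encodes phosphoenolpyruvate carboxykinase. Among the 10 domains, it had the smallest change in dim-5 (−0.04), and its changes in hpo and dim-3 were −0.021 and −0.018. The domain at IV 2330001 to 2400000, with the phosphate permease gene pho-5 (NCU08325), had −0.51 in dim-3. The other 7 of the 10 lie at I 3590001 to 3690000, I 6380001 to 6480000, I 2270001 to 2350000, I 4020001 to 4100000, I 8220001 to 8300000, III 300001 to 380000 and II 3600001 to 3720000.

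**Figure D3:**
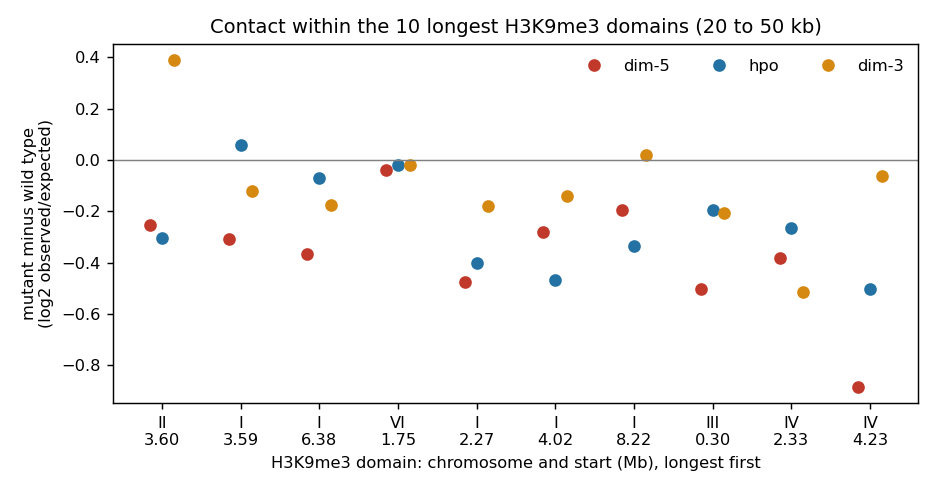
Difference from wild type (log2 observed over expected) in contact between bins 20 to 50 kb apart within each of the 10 longest H3K9me3 domains, named by chromosome and start in Mb on the x axis, with 1 point per mutant. All 10 points of dim-5 and 9 of 10 points of hpo lie below 0.

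The fourth comparison asked whether separate H3K9me3 regions keep meeting one another. In wild type, H3K9me3 bins contacted each other more than other bins, both at 100 kb or more on 1 chromosome (0.46 ± 0.14) and between chromosomes (0.98 ± 0.20), and they contacted euchromatin on the same chromosome less (−0.29 ± 0.09). Contact of H3K9me3 bins between chromosomes differed from wild type by −0.01 ± 0.06 in dim-5 and −0.02 ± 0.04 in hpo, intervals that hold 0, while 4 of 200 shifts gave a value as low as that of hpo and the ratio arrays of all reads gave −0.093 and −0.098. Relative to the mean between chromosomes, it fell in dim-3 (−0.23 ± 0.10, lower in 21 of 21 chromosome pairs). Because that mean was a larger part of a bin's total in dim-3, this contact was not lower as a part of the total. On 1 chromosome the differences were 0.05 ± 0.05 in dim-5, an interval that holds 0 although 0 of 200 shifts gave a value as high, −0.07 ± 0.06 in hpo and 0.07 ± 0.06 in dim-3. The ratio arrays of all reads gave −0.078 in dim-5 and −0.20 in hpo, and medians of single pairs of bins gave −0.65 and −1.95. The difference between dim-5 and hpo was 0.11 ± 0.10.

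Contact between H3K9me3 bins and euchromatin on 1 chromosome rose slightly in all 3 mutants, by 0.07 ± 0.02 in dim-5 and 0.09 ± 0.02 in hpo, each on all 7 chromosomes, and by 0.06 ± 0.05 in dim-3. Several of these values turned direction with the processing: as medians of single pairs of bins, the wild-type enrichments of H3K9me3 contact were −0.42 on 1 chromosome and −1.34 between chromosomes, and the differences in contact with euchromatin were −0.64 in dim-5 and −1.29 in hpo. Such a median is divided by a mean, so in sparse arrays it tends to lie below 0. In wild type it was −0.76 even for euchromatin between chromosomes. Its sign does not show that H3K9me3 bins met less than other bins, and its differences can also reflect how sparse each array is. In the ratio arrays of all reads, the dim-3 difference in H3K9me3 contact on 1 chromosome was −0.17 and the dim-5 difference in contact with euchromatin −0.0030, while against the wild-type ratio array with the fewest reads the dim-3 difference in H3K9me3 contact between chromosomes was 0.092.

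In wild type, contact between H3K9me3 bins grew with distance relative to expectation, from 0.0010 at 100 to 300 kb and 0.43 at 300 to 1000 kb to 0.66 at 1000 to 3000 kb and 1.28 at 3000 to 10000 kb. The dim-5 difference was 0.113 ± 0.053 at 100 to 300 kb and 0.116 ± 0.115 at 300 to 1000 kb. The hpo difference was −0.066 ± 0.056 at 300 to 1000 kb and −0.103 ± 0.030 at 3000 to 10000 kb. The intervals of the other distances hold 0 in these strains, as do those of dim-3 at all 4. Pairs of single domains were too sparse to compare 1 by 1. Of 1239 pairs of domains, 1162 in dim-5, 1141 in hpo and 1124 in dim-3 had contact in both the mutant and wild type. Over these the median change was 0.01 in dim-5, −0.10 in hpo and −0.01 in dim-3, with standard deviations of 1.37, 1.24 and 1.42. The pairs with the largest changes included VI 1070001 to 1090000 with VI 3400001 to 3420000, where observed over expected contact was 2.37 in wild type and 0.038 in dim-5. In 27 of the 30 pairs chosen by size of change, at most 2 pairs of bins held contact in the strain with the lower value.

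The leading principal component of each chromosome's contact pattern was compared with H3K9me3. Its sign on each chromosome was set by H3K9me3. A positive correlation was thus favoured beforehand, and its sign is no evidence that the component follows the mark. Across bins, which are not independent replicates, Spearman's rho between the component and H3K9me3 was 0.39 ± 0.13 in wild type, from 0.17 on chromosome IV to 0.54 on VII. These bins include the centromeres, whose mean H3K9me3 signal was 16.9. In wild type the mean component was 1.06 in centromere bins and −0.08 in interstitial H3K9me3 bins. It was −0.30 in H3K27me3, −0.37 in telomere and −0.84 in euchromatin bins. The component was thus highest at centromeres, and rho does not describe interstitial H3K9me3 alone. The differences in rho were 0.01 ± 0.04 in dim-5, −0.04 ± 0.04 in hpo and 0.03 ± 0.07 in dim-3, and all 3 intervals hold 0. In the ratio arrays of all reads the differences were −0.082 in hpo and −0.13 in dim-3.

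The fifth comparison covered H3K27me3, the mark of facultative heterochromatin. In wild type, H3K27me3 bins at least 100 kb apart on 1 chromosome contacted each other more than other bins (0.54 ± 0.27). This contact fell in dim-5 (−0.10 ± 0.10) and dim-3 (−0.10 ± 0.07), in 6 of 7 chromosomes each, and the interval of hpo holds 0 (0.0032 ± 0.04). The dim-5 interval barely excludes 0, and 8 of 200 random shifts of the marked bins along the chromosomes gave a difference as low. In the ratio arrays of all reads the dim-3 difference was 0.035.

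The longest H3K27me3 domain, at IV 460001 to 810000, spanned 350 kb with 97 genes, among them the glutamine synthetase gene gln-2, the polyketide synthase gene pks-3 and the glycoside hydrolase gene gh7-2. Others in the list of 10 held further glycoside hydrolase genes, gh7-1 at VI 3800001 to 3930000, gh11-2 at V 6150001 to 6270000 and gh7-4 at VI 3700001 to 3780000. Unlike in H3K9me3 domains, contact within these 10 domains had no common direction: it was lower in 5 of 10 in dim-5, 6 of 10 in hpo and 4 of 10 in dim-3, with medians of −0.01, −0.02 and 0.06.

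**Figure D4:**
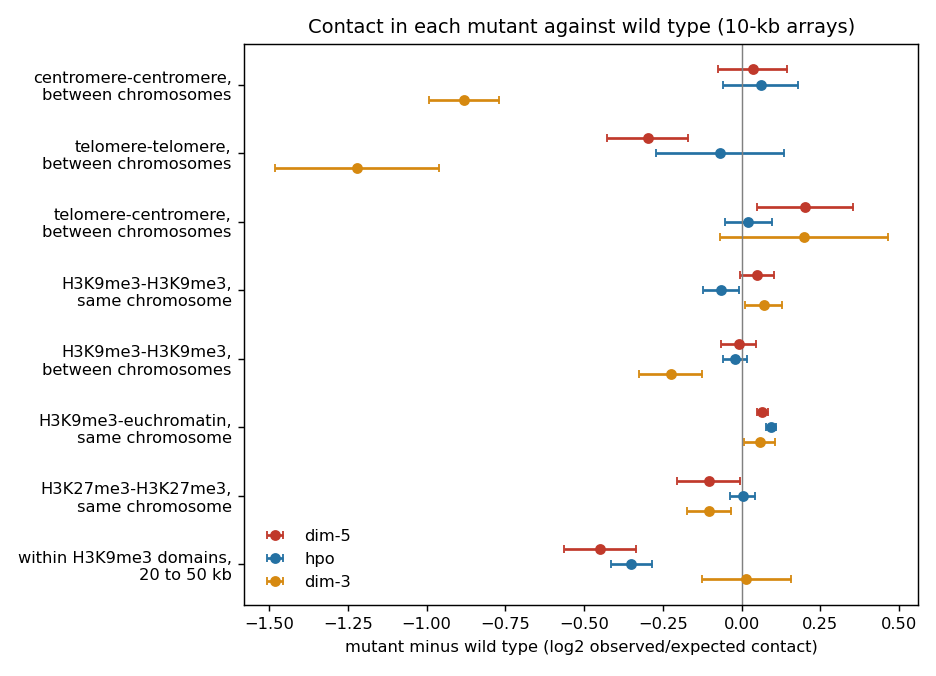
Difference from wild type in 8 classes of contact (log2 observed over expected, x axis) in the 3 mutants; points are the values from the 10-kb arrays and bars are 95% jackknife intervals over the 7 chromosomes. The losses of centromere and telomere contact in dim-3 (−0.88 and −1.22) and of contact within H3K9me3 domains in dim-5 and hpo (−0.45 and −0.35) lie farthest from 0.

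The last comparison concerned the folding of whole chromosomes. Contact fell with distance between 50 kb and 1 Mb with an exponent of −1.15 ± 0.01 in wild type. The exponent changed by 0.01 ± 0.02 in dim-5 and −0.0021 ± 0.01 in hpo, intervals that hold 0. In dim-3 the decay was shallower by 0.22 ± 0.01. Contacts between chromosomes made up 50.6% ± 4.53 of the wild-type total. This share rose by 17.9 ± 2.15 percentage points in dim-3 and by 1.31 ± 0.60 in dim-5, and the hpo difference was 0.40 ± 0.61. Random ligation, which was not measured, can raise this share and can also make the decay shallower. At the last distance step (mean 889 kb), contact was 0.373 in dim-3, against a mean of 0.203 between chromosomes. In wild type it was 1.49 against 0.473. A part played by such background in the dim-3 exponent therefore stays open. Between 20 and 500 kb the dim-3 difference in exponent was 0.12.

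**Figure D5:**
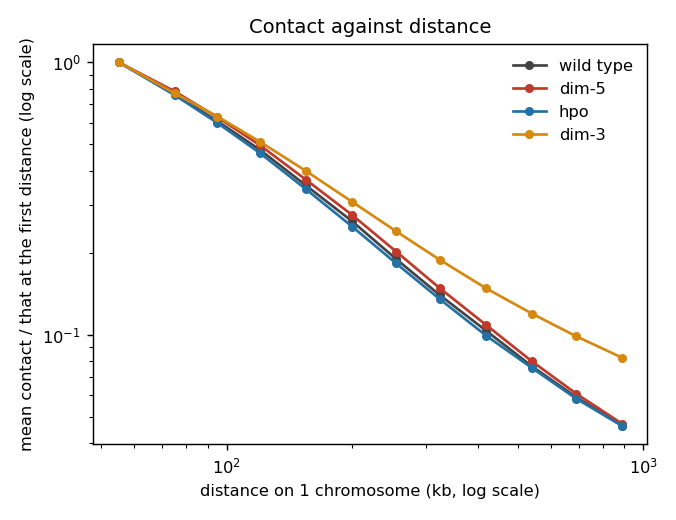
Mean contact between bins of 1 chromosome against their distance in kb, relative to the mean at the first distance, on log scales, in the 4 strains. The curve of dim-3 is shallower (difference in exponent 0.22), and those of the other 3 strains nearly overlap.

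The bins of 12 genes for DNA methylation, histone methylation and CenH3 were also examined. Of these, 11 lay in usable bins, and 10 of the 11 were euchromatin. The exception was suz12, a gene for H3K27 methylation, at II 1672115 to 1675786, whose bin had an H3K27me3 signal of 79.8. In wild type their enrichment in contact with H3K9me3 bins ranged from −0.59 for cul4, a ubiquitin ligase scaffold gene, to 0.04 for eed, a gene for H3K27 methylation. The bin of hpo itself (VI 2175752 to 2178135) was left out, as a bin without contacts in at least 1 of the 4 arrays. A deleted gene is smaller than a 10-kb bin, so these values do not check the strain labels.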

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

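The search for contacts of unplaced sequence and the choice of both target regions were made after the arrays were seen, while the tests of both explanations were set before their values were seen.

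The arrays hold 64 bins of sequence not placed on a chromosome, which no comparison above used, and 29 of them had contacts in all 4 strains. In wild type, 11 of the 29 had their strongest contact with the first 200 kb of chromosome V, at log2 4.35 over the mean between chromosomes within 100 kb of the strongest bin. The RefSeq table lists 135 genes on unplaced sequence, all of them rRNA genes. Another 15 bins had their strongest contact with chromosome I between 6200001 and 6600000, at 4.69 within 100 kb of the strongest bin (6390001 to 6400000), which lies in the H3K9me3 domain at 6380001 to 6480000. The contact at that bin was 5.51 in wild type, 5.25 in dim-5, 5.64 in hpo and 3.74 in dim-3.

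For the contact with chromosome I, the median contact of bins 100 to 500 kb from the strongest bin was at least 1.01 (log2) above the mean between chromosomes in each of the 4 strains. A value near that mean had been set as the mark of reads shared between copies of a repeat, but this bound was wrong, because reads of a copy at this locus that are assigned to unplaced sequence carry the contacts of the locus with its own surroundings. Contact fell with distance from the strongest bin with an exponent that differed from that of pairs on 1 chromosome by at most 0.19 in any strain, which is consistent with unplaced sequence lying next to that part of chromosome I and equally with such shared reads. The explanations cannot be told apart without the genome sequence, and adjacency stays a hypothesis about the assembly. The design gives no biological explanation for a contact shared by all 4 strains, and none was tested.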

How the results depend on the processing

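The settings named last in the list of alternatives (left end of chromosome V, wild type at 30 M reads, poorly filled bins left out at the fewest reads, strong pairs left out) were chosen after the data were seen, as were all contacts of other classes of bins. Of 408 alternative values of the 33 planned comparisons, 357 lay within the jackknife interval of the reported value, 43 lay outside it with no change in the direction of a called difference, and 8 reversed a called difference. Of the 17 called differences, 12 kept their direction under every alternative that gave a value. The 357 include all 231 values with 1 chromosome left out. The interval is computed from those values, so their place within it is no check. Unless stated, values are log2 differences from wild type, and the cause was not tested. Main dim-3 differences not given elsewhere were −0.16 ± 0.15 for H3K9me3 with centromeres, −0.23 ± 0.15 with telomeres and −0.055 ± 0.029 with H3K27me3 on 1 chromosome. For euchromatin between chromosomes they were −0.036 ± 0.016 in dim-5 and −0.033 ± 0.012 in hpo. With the authors' ratios for all reads, dim-3 had −0.65 for centromeres, −0.92 for telomeres, −0.17 (reversed) for H3K9me3 on 1 chromosome, 0.035 (reversed) for H3K27me3, 0.044 (reversed) for H3K9me3 with centromeres and −0.13 for the leading component. For H3K9me3 on 1 chromosome, H3K9me3 between chromosomes, H3K9me3 with euchromatin, euchromatin with centromeres and euchromatin between chromosomes, dim-5 had −0.078, −0.093, −0.0030 (reversed), −0.0065 (reversed) and 0.0044 (reversed), and hpo had −0.20, −0.098, 0.033, −0.080 (reversed) and 0.0075 (reversed), with −0.082 for the leading component and −0.11 for telomeres with centromeres. In the setting called similar numbers of reads, dim-3, set against the sparser wild type of 16.5 M reads, had −0.34 for centromeres, −0.66 for telomeres, 0.81 for telomeres with centromeres, 0.49 for H3K9me3 on 1 chromosome, 0.092 (reversed) between chromosomes, 0.20 with euchromatin, 0.48 (reversed) with centromeres, 0.22 (reversed) with telomeres, 0.29 (reversed) with H3K27me3, 0.76 within H3K9me3 domains and 0.030 (reversed) for H3K27me3. There dim-5 had −0.025 for H3K9me3 on 1 chromosome, −0.066 between chromosomes and 0.015 with euchromatin. In the same setting hpo, set against wild type with all reads and so not matched in depth, had −0.20, −0.098 and 0.031, with −0.12 for telomeres with centromeres, −0.086 (reversed) for euchromatin with centromeres and 0.0083 (reversed) for euchromatin between chromosomes. Against wild type at 30 M reads dim-3 had −0.63 for centromeres and −0.92 for telomeres, and at the fewest reads with poorly filled bins left out −0.58 and −0.76. The 50-kb arrays gave H3K9me3 with euchromatin 0.024 in dim-5 and 0.054 in hpo, and in dim-3 0.0081 (reversed) for H3K9me3 with centromeres and 14.04 percentage points for the share between chromosomes, which was 15.5 without pairs under 50 kb. The CenH3 peak gave −0.999 for centromeres in dim-3 and −0.098 for telomeres with centromeres in hpo. Marked bins by rank gave 0.083 in dim-5 and 0.12 in hpo for H3K9me3 with euchromatin. From 20 to 500 kb the exponent differed by 0.12 in dim-3 and 0.044 in dim-5. At 300 kb or more, H3K9me3 contact on 1 chromosome in dim-3 was −0.018 (reversed). Medians of single pairs of bins gave telomeres −2.10 in dim-3, H3K27me3 −0.91 in dim-3 and −0.16 in hpo, H3K9me3 on 1 chromosome −0.65 in dim-5 and −1.95 in hpo, H3K9me3 with euchromatin −0.64 and −1.29 (both reversed), within H3K9me3 domains −0.27 in hpo, and H3K27me3 with H3K9me3 −0.48 (reversed) in dim-5. Wild-type medians that reversed were −1.34 and −0.42 for H3K9me3 between and within chromosomes, −6.12 with centromeres, −1.87 with telomeres, −0.68 for H3K27me3 between chromosomes, −0.30 for H3K27me3 with euchromatin, and −0.76 and −0.080 for euchromatin between and within chromosomes. Medians are divided by a mean expected contact, so in sparse arrays they tend to lie below 0, and these values do not show depletion against other bins. The median gave no value for 8 of the 33 comparisons, where the median pair of bins was empty in a strain. Of 744 other values, which again include those with 1 chromosome left out, 651 lay within the interval and 20 reversed. Depth is unknown, and the share of empty pairs (42.0% in wild type, 64.7% in dim-3) limits what single pairs of domains can show. Replicates could not be left out, since they are pooled.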

Other observations

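The contacts across domains, of single strong pairs, by arm position and with other classes of bins, the test of a uniform background, the test of depth as the whole cause, the test of depth in hpo, the comparison with euchromatin and the relation with H3K9me3 after allowing for length and wild-type contact were chosen after the results they concern were seen.

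Euchromatin on either side of an H3K9me3 domain met more often in wild type than euchromatin the same distance apart without a domain in between. Over pairs 50 to 150 kb apart, the excess was 0.28 ± 0.09 (log2; 5462 pairs across any of 141 domains against 19002 other pairs). It was 0.05 ± 0.07 in dim-5 and 0.17 ± 0.07 in hpo, differences of −0.23 ± 0.06 and −0.11 ± 0.04, and in dim-3 the difference was −0.01 ± 0.01. Over 11 alternatives each, the dim-5 difference ranged from −0.28 to −0.18 and the hpo difference from −0.14 to −0.10. Most of these alternatives are the values with each chromosome left out in turn, from which the interval is computed, so they are no separate check. Between chromosomes, 816 of 5534654 pairs of interstitial bins stood more than 16-fold above the mean in all 4 strains, the rule by which they were chosen. In 792 of the 816 both bins were H3K9me3 bins by the track of the other study, and dim-5, which lacks the enzyme for that mark, is among the 4 strains. Without them the wild-type enrichment of H3K9me3 contact between chromosomes was 0.79, against 0.98 with them. Repeats, AT content and the density of HindIII sites were not tested for either value or for the strong pairs, since no genome sequence was used.

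Chromosome arms lined up by distance from the centromere in wild type. Positions 50 to 250 kb from the centromeres of different chromosomes were enriched in contact with each other (1.75) and depleted in contact with positions 2000 to 6000 kb away (−1.16). In dim-3 these values moved toward 0, by −0.80 ± 0.09 and 0.79 ± 0.06, and contact between euchromatin and centromeres of other chromosomes rose by 0.42 ± 0.05 (21 of 21 chromosome pairs). That contact also rose in dim-5 (0.10 ± 0.05, 19 of 21 pairs) and hpo (0.06 ± 0.04, 16 of 21), but the ratio arrays of all reads gave −0.0065 and −0.080. The dim-3 rise is not independent of the fall in contact among centromeres. All bins of an array have the same total, so contact lost there must be made up elsewhere. H3K27me3 bins also met the ends of other chromosomes in wild type (0.94 ± 0.19). Relative to the mean between chromosomes, this fell in dim-3 (−0.62 ± 0.18, in 21 of 21 chromosome pairs) with no change detected in dim-5 (−0.05 ± 0.09) or hpo (−0.02 ± 0.08). As a part of a bin's total the dim-3 fall was much smaller, because that mean was a larger part of the total in dim-3. In dim-5, contact between H3K27me3 and H3K9me3 bins on 1 chromosome rose by 0.12 ± 0.05 on all 7 chromosomes, but the median of single pairs was −0.48.

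Centromere IV was thinly covered, with 13 of 20 bins usable in all strains. Contact across the left boundary of the reversed segment on chromosome VI in the deposited order ranged from −0.22 in dim-3 to −0.052 in dim-5, and across the right boundary from −1.65 in wild type to −0.82 in hpo.

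The lower centromere and telomere contact in dim-3 was weighed against depth and background. Against wild type sampled to the fewest reads the centromere difference was −0.34 ± 0.10, between the bounds set beforehand, so a part played by depth cannot be told apart from the strain in that test, and that wild-type array was filtered differently. As the whole cause depth is argued against, since the difference was −0.63 ± 0.08 against wild type sampled to 30 M reads, and since these sampled arrays, with 60.9% and 73.2% of pairs empty, bracket the 64.6% of dim-3. A uniform background of random contacts would need to make up 65.0% of contacts between chromosomes to account for telomeres, 49.8% for centromeres and 29.4% for H3K9me3 bins, and the telomere share exceeded the H3K9me3 share by 35.6 ± 6.82 points, so 1 uniform share does not account for all of them. A background that adds to a loss of clustering, or a difference between libraries, may contribute and stays open, as does the dim-3 mutation itself, because each strain has 1 array.

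For the loss of contact within H3K9me3 domains, the ratio arrays gave a dim-5 difference of −0.43 both for all reads and with both strains sampled to 30 M reads, and a hpo difference of −0.35 ± 0.08 for all hpo reads against wild type sampled to 30 M reads (60.9% of pairs empty, against 59.1% in hpo), which argues against depth as the cause. The wild-type ratio array of 16.5 M reads, which is sparser and was filtered differently, had −0.67 within domains against 0.08 for all reads, so fewer reads still or that filtering can lower this value. Euchromatin at the same distances changed by 0.03 ± 0.02 in dim-5, and the domains lost more than euchromatin by a difference of −0.48 ± 0.12. The values of each strain are relative to its own mean at the same distance, to which euchromatin gives most bins. A change of the whole genome alike is thus divided out beforehand, so this comparison cannot test it. It shows a loss in the domains relative to euchromatin. Across 74 domains of at least 3 bins, the dim-5 change was more negative where H3K9me3 was higher (Spearman's rho −0.33, with the 5th percentile of 1000 shuffles at −0.19), which is consistent with a loss that follows the mark (rho −0.30 in hpo and 0.27 in dim-3), but the dim-5 change was also more negative in shorter domains (rho 0.39) and where wild-type contact was higher (rho −0.53, which noise in the wild-type values alone can give), and after allowing for both the partial rho with H3K9me3 was −0.37 in dim-5, −0.31 in hpo and, with the opposite sign and also beyond the shuffles, 0.26 in dim-3, where no overall loss was detected. That H3K9me3 and HP1 may favour contact inside these domains is a hypothesis found and tested on the same data, and a difference between libraries stays open.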
